A study of Homo sapiens with 8 samples.

How the data were processed

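Total RNA was measured by RNA-seq in A2058 and C8161, human melanoma cell lines. Per the labels' protocols, ATF3 was introduced by retroviral transduction, control cells carried neomycin resistance, cells were grown in DMEM with 10% fetal bovine serum, RNA was isolated with a column kit, and libraries were made for DNA nanoball sequencing. The labels give 1 library for each A2058 arm and 3 for each C8161 arm, 8 in all. They do not say whether the C8161 libraries came from separate transductions or cultures.

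The authors deposited 1 table of RPKM values, per the file headers, with 18478 Entrez gene identifiers and 2 decimals. Bowtie2, RSEM and the build hg38 are named per the submitters' processing notes, without versions. The annotation, the filters and the strand setting are not given in the sources used here. RSEM itself reports FPKM, and whether the authors' RPKM count reads or fragments is not stated. Of the 4 value columns, 2 hold the A2058 libraries and 2 hold combined values that the headers mark as covering the whole C8161 arm. Whether these are means or values from pooled reads is not stated, so they are reported as the authors' combined values without SD or n. A value per gene does not separate reads of the introduced ATF3 copy from those of the cell's own gene.

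The column sums were 476236 RPKM (A2058 with ATF3), 470633 (A2058 control), 472590 (C8161 with ATF3) and 481302 (C8161 control). The 10 most abundant genes took 6.27%, 6.28%, 7.09% and 7.34% of these sums. Depth was estimated from the low values: in genes with transcripts of 400 to 1500 bases, the value times the length should fall on whole multiples of what 1 read is worth. The A2058 columns had such steps, with a coherence of 0.413 and 0.427 against at most 0.193 and 0.252 in 100 shuffles of the lengths, which gives about 18000000 and 17900000 reads. This estimate is approximate, since the authors' transcript lengths are unknown. In the C8161 columns the coherence (0.132 and 0.133) stayed under that of shuffled lengths (0.271 and 0.222). No counts were recovered.

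Gene symbols, types and coordinates came from the RefSeq genes of GRCh38.p14, the assembly of the authors' build, matched on the Entrez identifier. Of the identifiers, 18156 had a symbol and 322 did not; 17731 were protein-coding. GC content, length and shared sequence were taken from GENCODE 29 transcripts, available for 17847 genes. A gene was called shared where at least 50% of the 50-base stretches of its longest transcript also occur in transcripts of another gene.

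The tests planned before the data were examined needed a value per library: limma for C8161, camera for the gene lists, an interaction term for the difference between lines, and an exact permutation test of ATF3. With 1 value per arm none of them could be run, and the descriptions planned for the unreplicated A2058 pair were used for both lines. Values were used as deposited. The ratio of a gene was log2(RPKM + 1) with ATF3 minus that in the neomycin control, over genes with at least 1 RPKM in at least 1 of the 2 columns of a line. Folds of RPKM without the added 1 are given where stated. Each ratio was set beside its level band, the central 95% of the ratios of the 500 genes nearest in mean level. The band describes the spread across genes of 1 pair of columns, which holds counting error, technical differences and biology together, and is not a test.

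For each of 31 gene lists fixed beforehand, the median ratio was expressed as a percentile among 10000 random lists of the same size, matched on mean level in 10 bins. Lists with fewer than 5 genes compared got no percentile. Members of a pathway vary together, so random lists understate the spread of a list median and percentiles near 0 or 100 are not p-values. The difference between lines was treated likewise. Level bands and list percentiles were tested on simulated data drawn for each comparison. For A2058 (11873 genes) 99% of genes changed 2.5-fold and 97% of those changed 1.5-fold lay outside the band, as did 3.63% of unchanged genes; for C8161 (10959 genes) these were 100%, 100% and 3.46%. A list raised 1.15-fold lay at percentile 100 in both, and 5% (A2058) and 4% (C8161) of unchanged lists lay outside the central 95%. The unchanged lists were themselves random draws of the simulated genes, so a share near 5% was fixed in advance. These checks do not cover spread beyond counting error or genes that vary together.

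The genes named were chosen by a rule written before the data were examined, with size in place of the missing test: ATF3; the 10 highest and 10 lowest log2 ratios in C8161 with a mean of at least 2 RPKM; up to 4 members of each list with the largest absolute ratio in C8161 at that level; up to 6 genes per direction with the largest smaller ratio of the same sign in both lines; the 5 highest and 5 lowest in A2058; and the 5 with the largest difference between lines. Genes without a symbol and genes of the Y chromosome are not named. Other genes are named with the remark that they were chosen after their values were seen.

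Alternatives were pseudocounts of 0.1 and 0.5, quantile normalization, median-ratio scaling, no minimum level and a minimum of 5 RPKM. Chosen after seeing the data were a size of 0.5 in place of 1 on the log2 scale, leaving out genes of shared sequence or without a transcript, the list percentiles in C8161, and a correction of the ratios by lowess (fraction 0.3) on GC content and then on length. Corrected ratios of single genes were set beside the level bands of the uncorrected ratios. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.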

Results

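RNA-seq was analysed from A2058 and C8161, established human melanoma cell lines, each with retrovirally introduced ATF3 or with a neomycin control. ATF3 encodes activating transcription factor 3, a stress-inducible transcription factor of the ATF/CREB family. The series holds 8 libraries, 1 per arm for A2058 and 3 per arm for C8161. The authors' table gives RPKM, a read count scaled to transcript length and library size, for 18478 genes, in 1 column per A2058 library and 1 combined column per C8161 arm. There was therefore no replicate spread for any comparison, no test was run, and every difference below describes these values alone. Low values in the A2058 columns lay on steps of whole reads that place their depth at about 18000000 reads with ATF3 and 17900000 reads in the control, where 1 read on a transcript of 1 kb is worth about 0.056 RPKM. The combined C8161 columns showed no such steps within the range of depths searched. Reads pooled from 3 libraries of the A2058 depth would lie above that range, so the depth of these columns is unknown. In the 4 columns, 10866 to 11753 genes reached 1 RPKM.

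ATF3 (Entrez gene 467; chromosome 1, 212565407 to 212620777, GRCh38) was higher with the introduced gene in both lines. In C8161 its level was 62.6 RPKM against 4.76 RPKM in the control, 13.1-fold higher. In A2058 it was 4.71 RPKM against 1.22 RPKM, 3.86-fold higher. The ATF3 level of the transduced A2058 cells thus lay beside that of the C8161 control cells. On the log2(RPKM + 1) scale used for all other ratios, which understates differences of low genes, the log2 ratios were 3.46 in C8161 and 1.36 in A2058.

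The first comparison asks which transcripts differ between C8161 cells with introduced ATF3 and their neomycin controls. Few genes differed strongly. Of 10941 genes compared, ATF3 included, 3 were higher and 1 was lower by a log2 ratio of 1 or more. At 0.5 or more, a size chosen after the data were seen, 20 were higher and 10 lower, again with ATF3 included. CDH5, which encodes the endothelial adhesion molecule VE-cadherin (Entrez gene 1003; chromosome 16, 66366691 to 66404784), was at 18.1 RPKM with ATF3 against 8.86 RPKM, 2.05-fold higher. STC1, the secreted hormone stanniocalcin 1 (chromosome 8, 23841929 to 23854806), was at 8.42 against 5.11 RPKM. MYPN, the sarcomeric protein myopalladin, was at 3.96 against 2.24 RPKM, and IL24, a cytokine of the interleukin 10 family, was at 5.13 against 3.19 RPKM. Among the lower genes, BIK, a pro-apoptotic BH3-only protein (chromosome 22, 43110750 to 43129712), was at 3.64 RPKM with ATF3 against 6.23 RPKM, and TGFBI, an extracellular matrix protein induced by TGF-beta (chromosome 5, 136028988 to 136063818), was at 155 against 220 RPKM. NBL1, a secreted BMP antagonist, was at 10.7 against 16.7 RPKM, PRR7 at 7.27 against 10.8 RPKM, CYS1 at 7.35 against 10.8 RPKM, NAPRT at 1.52 against 2.52 RPKM and PDXDC1 at 5.23 against 7.67 RPKM. Each of these genes lay outside the central 95% of the log2 ratios of the 500 genes nearest to it in level, a range called the level band here, which by construction leaves about 2.5% of genes outside on each side. After removal of the trends with GC content and length, described below, the log2 ratio of PRR7 moved from −0.52 to −0.28, that of NAPRT from −0.48 to −0.30 and that of NBL1 from −0.61 to −0.45. PRR7 then lay inside its band, whereas NAPRT and NBL1 stayed below theirs. Here and below, ratios after removal are set beside the bands of the ratios before it. Those bands are somewhat wide for this use. At 20 RPKM or more in C8161 the SD of the ratios was 0.145 before and 0.129 after removal. Places near an edge, as that of PRR7, are therefore uncertain.

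The genes past a log2 ratio of 1 in C8161 other than ATF3, named after their values were seen, were MSMP (2.48 RPKM with ATF3 against 0.50), the read-through gene ABHD14A-ACY1 (2.09 against 0.50) and, in the other direction, the read-through gene FMC1-LUC7L2 (1.19 against 3.65). MSMP shares 0% of its sequence with another gene, whereas both read-through genes share most of theirs. Several further genes with large ratios also have most of their transcript sequence in common with another gene, and their values are uncertain for that reason. They were RPS10-NUDT3 (3.37 against 1.62 RPKM), NPIPA5 (5.31 against 2.81) and SCHIP1 (10.3 against 6.33) among the higher genes, and LOC102724594 (3.26 against 5.75) and EIF3CL (19.2 against 27.6) among the lower ones. LOC102723728 (10.3 against 6.09 RPKM) and TMEM183BP (6.77 against 4.13) had no reference transcript with which this could be checked.

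Gene lists fixed before the data were examined showed small differences carried by many members. Of 28 lists with at least 5 genes compared in C8161, 8 had a median log2 ratio outside the central 95% of 10000 random lists matched on level, where 1.4 would be expected by chance if lists were independent of one another and their members of each other. The type I interferon response list had the highest median, 0.23 (percentile 100), with 19 of 20 members above 0 and 8 above their level band. OASL was at 3.94 RPKM with ATF3 against 2.38, IFI44 at 13.6 against 9.08, IFIT1 at 3.12 against 1.86, IFIT2 at 3.41 against 2.22 and IFIT3 at 10.35 against 7.54. The list of endoplasmic reticulum chaperones and other unfolded protein response genes had a median of 0.19 (percentile 100), with 23 of 26 members above 0 and 10 above their band. HSPA5, which encodes the chaperone BiP, was at 841 RPKM with ATF3 against 655, HSP90B1 (GRP94) at 943 against 746, HERPUD1, a component of ER-associated degradation, at 129 against 97.1, and MANF at 194 against 148.

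The integrated stress response list, whose genes act with or downstream of ATF4, had a median of 0.08 (percentile 99.7), with 21 of 27 members above 0. PPP1R15A, the phosphatase subunit GADD34, was at 101 RPKM with ATF3 against 76.7, DDIT4 at 27.6 against 23.1 and ATF5 at 23.7 against 19.6, whereas GDF15 was lower, at 4.45 against 5.99 (log2 ratio −0.36, and −0.21, inside its band, after removal of the GC and length trends). The AP-1 and ATF family had a median of 0.08 (percentile 98.7), with ATF6, a sensor of ER stress, at 29.2 against 24.6 RPKM and FOSL1 at 560 against 489, and with JUNB lower at 15.5 against 18.0. Removal of these trends took the log2 ratio of JUNB from −0.20 to −0.05 and that of FOSL1 from 0.20, inside its band, to 0.30, above it. It took ATF6 from 0.24, above its band, to 0.18, inside it, and raised the ratios of PPP1R15A, DDIT4 and ATF5. Cholesterol and lipid synthesis genes had a median of 0.10 (percentile 99.99), although only 16 of 27 members were above 0. STARD4 was at 15.6 against 12.1 RPKM, SCD at 222 against 186, INSIG1 at 32.8 against 27.4 and HMGCS1 at 18.2 against 15.3. With the trends removed, the log2 ratio of SCD went from 0.25 to 0.22 and that of HMGCS1 from 0.23 to 0.18. Both then lay inside their bands, whereas STARD4 stayed above its band. Genes of the G2 and M phases had a median of 0.06 (percentile 98.9), with 26 of 32 members above 0, among them MKI67 at 35.1 against 28.5 RPKM and CENPE at 5.36 against 4.20. With the trends removed, the log2 ratio of CENPE went from 0.29 to 0.23, inside its band, whereas MKI67 stayed above its band. Heat shock proteins had a median of 0.06 (percentile 98.4), with 15 of 21 members above 0. Once the trends of the ratio with GC content and length were removed, this last percentile was 96.0, with the median at 0.0578 against 0.0631 before, and the random lists' SD at 0.0296 against 0.0345.

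Ribosomal protein genes had the lowest list median in C8161, −0.15 (percentile 0), with 29 of 38 members below 0. RPLP1 was at 1899 RPKM with ATF3 against 2429, RPLP2 at 1381 against 1728, RPL18 at 707 against 923 and RPS15 at 523 against 673. The log2 ratio of RPS15 moved from −0.36 to −0.16 and that of RPLP2 from −0.32 to −0.18 after removal of the trends with GC content and length. The list median was −0.06 (percentile 0.11) after removal of the trends with GC content and length, and −0.04 after quantile normalization, where its percentile of 3.55 no longer lay outside the central 95%.

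**Figure D1:**
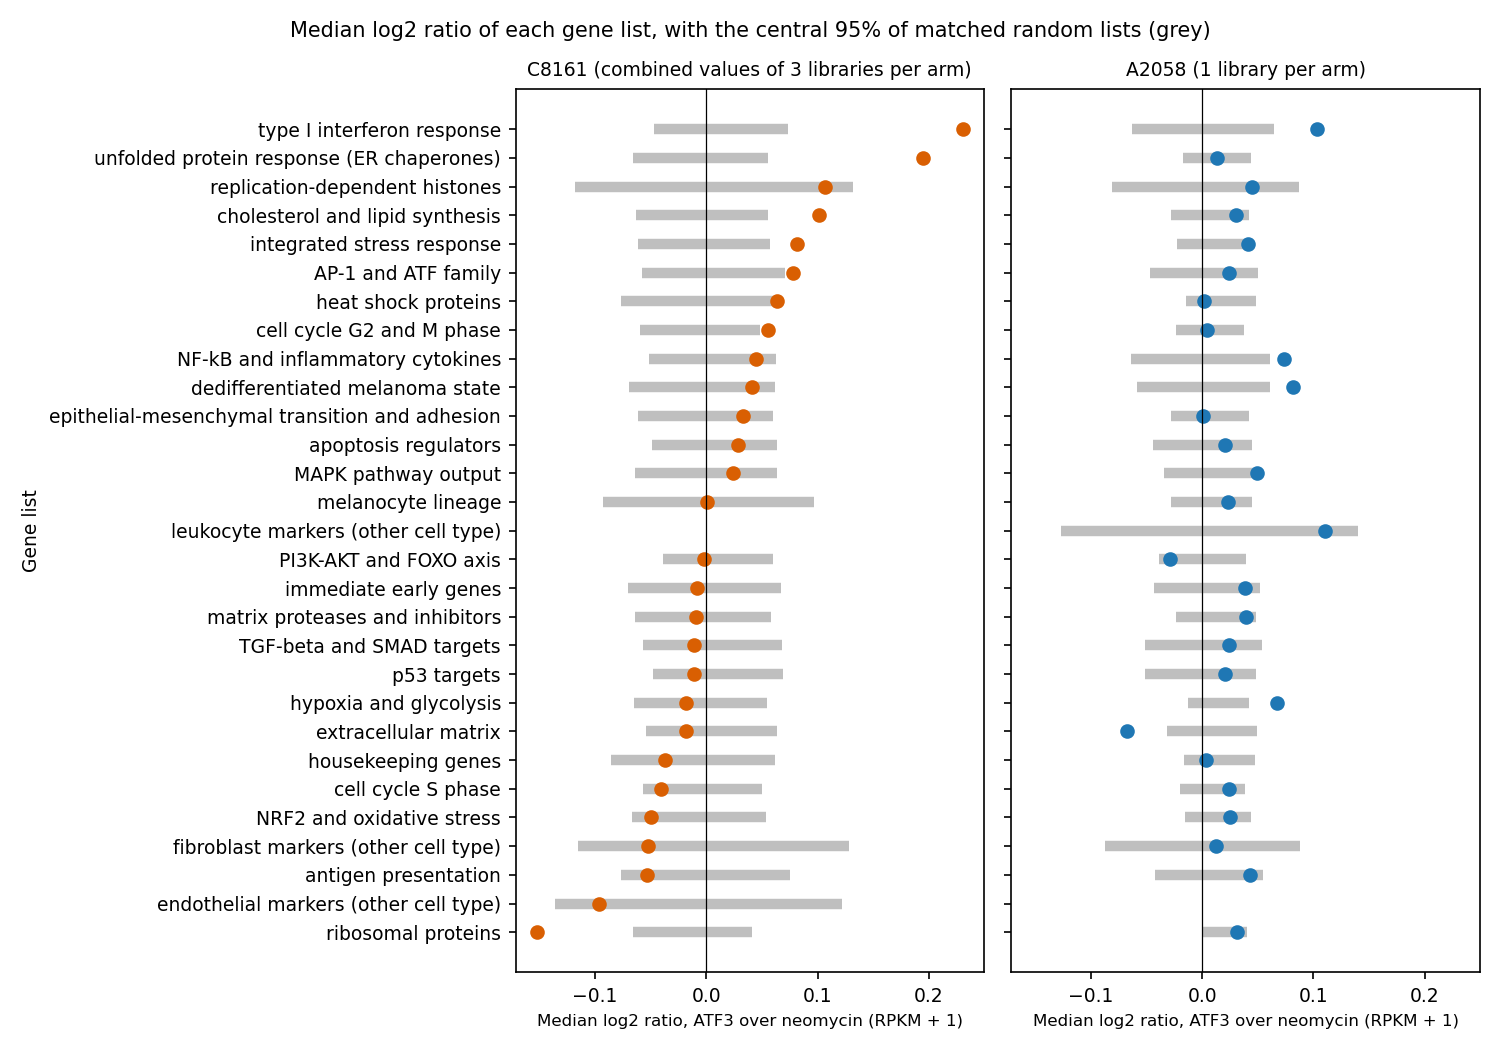
Median log2 ratio of ATF3 over neomycin (x axis, log2 of RPKM + 1, no unit) for each gene list (y axis) in C8161 and A2058; grey bars span the central 95% of 10000 random lists matched on level. The interferon list lies to the right of its grey bar in both lines (0.23 and 0.10), whereas the unfolded protein response list (0.19 and 0.01) and the ribosomal list (−0.15 and 0.03) lie outside it in C8161 and inside it in A2058.

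The C8161 ratios also varied with GC content and transcript length. Across 10860 genes, which are not independent replicates, Spearman's rho of the ratio was −0.43 with GC content and 0.23 with the length of the longest transcript. The median log2 ratio was 0.06 in the tenth of genes of lowest GC content and −0.13 in the tenth of highest. In A2058 the same values of rho were 0.10 and −0.23 across 11757 genes. After removal of both trends, the C8161 lists of interferon, unfolded protein response, integrated stress response and cholesterol synthesis genes lay at percentiles of 100, 100, 99.9 and 99.6, and those of the AP-1 and ATF family and of the G2 and M phases at 99.7 and 98.4.

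**Figure D2:**
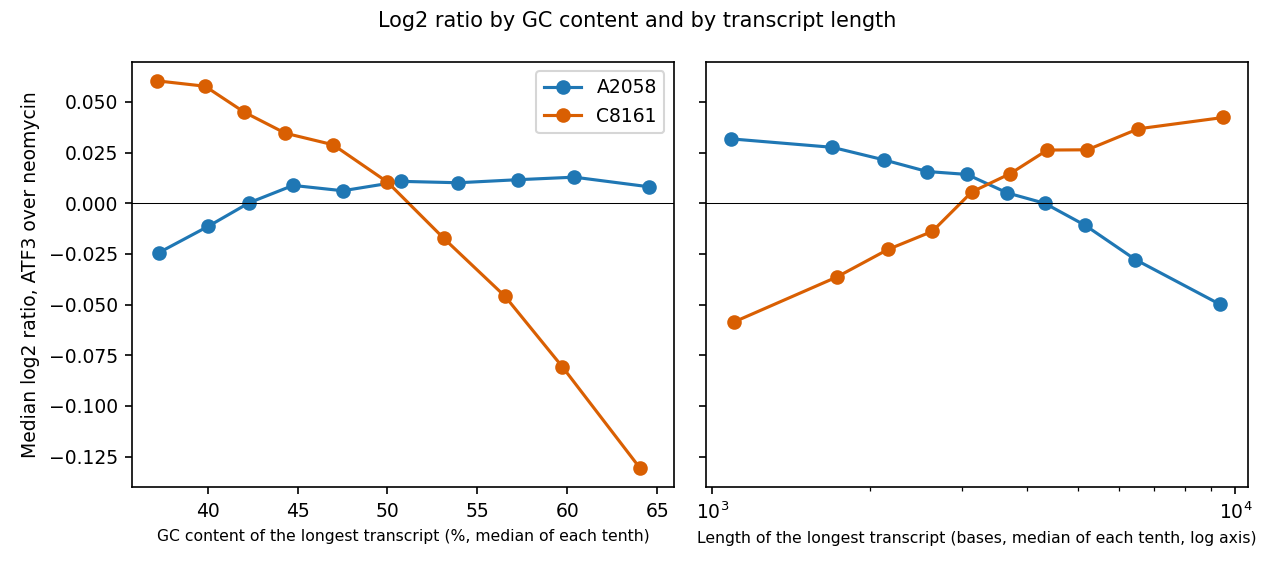
Median log2 ratio of ATF3 over neomycin (y axis) in 10 equal groups of genes by GC content (left, %) and by length (right, bases, log axis) of the longest transcript, for A2058 and C8161. In C8161 the median goes from 0.06 at the lowest to −0.13 at the highest GC content, and the slopes with length have opposite signs in the lines.

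The remaining lists lay inside the central 95% in C8161. Their medians were 0.11 for replication-dependent histones, 0.04 for NF-kB and inflammatory cytokines, 0.04 for the dedifferentiated melanoma state, 0.03 for epithelial-mesenchymal transition and adhesion, 0.03 for apoptosis regulators, 0.02 for MAPK pathway output, −0.04 for the S phase, −0.05 for NRF2 and oxidative stress and −0.05 for antigen presentation. They were within 0.02 of 0 for the melanocyte lineage, the PI3K-AKT and FOXO axis, immediate early genes, matrix proteases, TGF-beta and SMAD targets, p53 targets, hypoxia and glycolysis, and extracellular matrix, and −0.04 for housekeeping genes, which moved to 0.00 after quantile normalization, where the hypoxia median changed sign from −0.02 to 0.03. The NRF2 list, at percentile 7.57, had a median of −0.08 (percentile 1.31) with a pseudocount of 0.1 and of −0.07 (percentile 2.0) with a minimum of 5 RPKM. Single members stood apart in some of them, in both directions, and those given here are not all. CCNG2, a FOXO target, was at 5.88 RPKM with ATF3 against 3.89, the cell cycle inhibitor CDKN1A at 5.57 against 4.22, MMP2 at 31.2 against 23.7, PLAT at 8.5 against 6.21, IL6 at 3.82 against 2.66 and TNFAIP3 at 6.71 against 5.09. The E-cadherin repressor SNAI2 was lower, at 15.95 against 20.97 RPKM, as was GPX1, at 177 against 230, whose log2 ratio of −0.38 was −0.21, inside its band, after removal of the GC and length trends. PLK3, in the p53 list with CDKN1A, was also lower, at 4.08 against 5.21, as were PHLDA2 (134 against 168), TNC (46.46 against 58.75) and AKR1C1 (45.82 against 57.34). After that removal the log2 ratios of PLK3 and PHLDA2 were −0.18 and −0.16, inside their bands.

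For TGF-beta and SMAD targets in C8161 the median (−0.01, percentile 27.9) depended on the setting. The mean log2 ratio was −0.10, and 4 of 21 members lay below their band and none above. Besides TGFBI these were the inhibitors of differentiation ID1 (51.9 RPKM with ATF3 against 70.9), ID3 (36.0 against 46.4) and ID2 (1.67 against 2.22, named after its value was seen). The percentile was 0.24 without a minimum level, 1.17 with a minimum of 5 RPKM and 0.41 after removal of the GC and length trends. That removal also placed the S phase at 1.29, immediate early genes at 98.2, NF-kB and inflammatory cytokines at 99.0 and histones at 98.3.

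Marker lists of other cell types served as checks of the cultures. In C8161 the endothelial list had a median of −0.10 over 5 genes. CDH5 was higher as given above, as was ERG, named after its value was seen, at 1.36 RPKM with ATF3 against 0.86, both above their band, whereas TIE1 was at 62.8 RPKM against 67.2, ROBO4 at 18.1 against 20.5 and EGFL7 at 8.58 against 9.75. Fibroblast markers had a median of −0.05 in C8161 and 0.01 in A2058, and leukocyte markers had a median of 0.11 over 5 genes in A2058 (percentile 94.7), or of 0.10 over 14 genes without a minimum level (percentile 99.9). The leukocyte genes added without that minimum lay under 1 RPKM in both A2058 columns. There 1 read on a transcript of 1 kb is worth about 0.056 RPKM, so few reads decide these ratios. The leukocyte marker CD68 was above its band in C8161, at 37.58 RPKM with ATF3 against 29.03, but 89.7% of its sequence is shared with another gene. In A2058, ESAM (2.73 RPKM with ATF3 against 1.70), LYZ (2.07 against 1.28) and SFN (1.48 against 0.71) lay above their bands. EGFL7 (48.99 against 54.35) and FCER1G (0.39 against 1.17) lay below theirs. ESAM, LYZ and FCER1G were named after their values were seen. Keratinocyte markers in both lines, endothelial markers in A2058 and leukocyte markers in C8161 had fewer than 5 genes compared, and no mitochondrially encoded gene is listed in the table. Median and mean differed in sign for the endothelial, PI3K-AKT, melanocyte, dedifferentiated and matrix protease lists in C8161, and for the G2 and M phase, epithelial-mesenchymal transition and histone lists in A2058.

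The second comparison set the single A2058 library with introduced ATF3 against its control. Of 11883 genes compared, 6 were higher and 8 lower by a log2 ratio of 1 or more. ATF3 was the only one of the 14 that has a reference transcript with less than 50% of its sequence in common with another gene. SERF1A was at 5.24 RPKM with ATF3 and listed at 0 in the control, and FMC1-LUC7L2 was at 4.62 against 0.20. PEDS1-UBE2V1, another read-through gene, was at 0.41 RPKM against 7.81, and GAGE12D, a member of a cancer-testis antigen family with near-identical copies, at 8.51 against 18.3. CSAG2 (1.81 against 3.94), FAM72D (2.16 against 4.16) and LIMS4 (3.25 against 5.78) were also lower and also share most of their sequence.

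In A2058 the hypoxia and glycolysis list stood highest among the random lists. Its median log2 ratio was 0.07 (percentile 100), with 27 of 29 members above 0 and 5 above their band. Those 5, named after their values were seen, were NDRG1 (113 RPKM with ATF3 against 100.4), the neuronal enolase ENO2 (105 against 94.2), the glucose transporter SLC2A3 (39.1 against 35.1), ANKRD37 (27.4 against 23.7) and the oxygen sensor EGLN3 (2.19 against 1.45). The extracellular matrix list was lower, with a median of −0.07 (percentile 0.01) and 17 of 23 members below 0, and with a median of −0.04 (percentile 1.28) after removal of the trends with GC content and length. LAMA1, its single member below the band and named after its value was seen, was at 46.5 against 50.2 RPKM. It passed the band narrowly, with a log2 ratio of −0.108 against an edge of −0.106. The type I interferon list had a median of 0.10 (percentile 99.8), with 15 of 19 members above 0. IFIT3, at 6.17 against 4.71 RPKM, was its single member above the band.

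The other A2058 lists outside the central 95% were the dedifferentiated melanoma state (0.08, percentile 99.5), NF-kB and inflammatory cytokines (0.07, percentile 99.0) and MAPK pathway output (0.05, percentile 98.5). With a minimum of 5 RPKM these lay at percentiles of 49.7, 87.6 and 80.6. Members named after their values were seen were CCL5, at 4.10 RPKM with ATF3 against 2.82, IL11, at 4.44 against 3.51, and the urokinase receptor PLAUR, at 41.6 against 33.4. The lists of the integrated stress response (0.04, percentile 96.9), AP-1 and ATF family (0.02), cholesterol synthesis (0.03), unfolded protein response (0.01), heat shock (0.00), ribosomal proteins (0.03) and G2 and M phases (0.00) were inside. So were the S phase, melanocyte, p53, apoptosis, TGF-beta and NRF2 lists at 0.02 or 0.03, the immediate early, matrix protease and antigen presentation lists at 0.04, histones at 0.05, the PI3K-AKT list at −0.03, and adhesion and housekeeping genes at 0.00. After quantile normalization the unfolded protein response and ribosomal medians were no longer above 0. After removal of the GC and length trends the integrated stress response lay at percentile 99.2, the AP-1 and ATF family at 99.1 and MAPK pathway output at 93.7. The integrated stress response also lay outside after quantile normalization (percentile 97.81) and with a minimum of 5 RPKM (percentile 97.54).

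Between the lines, the ratios showed no positive correlation across genes, although the interferon list lay above the random lists in both. Without ATF3, Pearson's r between the A2058 and C8161 log2 ratios was −0.043 and Spearman's rho −0.046 across 10330 genes, which are not independent replicates. Among genes above the level band in C8161, 142 of 259 (54.8%) had a ratio above 0 in A2058, against 51.5% of genes inside the band at matched levels. Among genes below the band, 123 of 268 (45.9%) were below 0 in A2058, against 48.2%. Of the 259, 19 lay above the A2058 band and 11 below it, and of the 268, 11 lay above and 11 below. Of all 11883 genes compared in A2058, 319 lay above the band and 323 below. Besides ATF3, the genes that were higher in both lines by the largest smaller ratio and share little sequence with other genes were IFIT3, BCL3 and ASRGL1. BCL3, an atypical IkB protein, was at 7.52 RPKM with ATF3 against 5.67 in A2058 and at 8.56 against 6.62 in C8161. ASRGL1 was at 13.95 against 11.4 in A2058 and at 2.49 against 1.66 in C8161. CDKN1A lay above its band in A2058 too, at 18.0 against 14.8 RPKM.

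Genes lower in both lines by the same criterion were C11orf71, TPGS1 and ZNF414, besides MDP1, CHURC1-FNTB and ACY1, which share most of their sequence with another gene. C11orf71 was at 2.59 RPKM against 3.83 in A2058 and at 2.26 against 2.94 in C8161. ZNF414 was at 6.56 against 7.89 and at 4.48 against 6.16. TPGS1 was at 17.7 against 21.2 and at 8.92 against 10.8, but its C8161 log2 ratio of −0.25 was 0.02 after removal of the GC and length trends.

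The difference of the ratios between the lines could not be tested without replicate values. As a description, the median difference, C8161 minus A2058, was 0.16 for the unfolded protein response list (percentile 100 among matched random lists), with 22 of 26 members higher in C8161. It was 0.14 for the interferon list (percentile 99.1, 13 of 16 members) and −0.18 for ribosomal proteins (percentile 0.01, 6 of 38 members higher). Outside the central 95% were also replication-dependent histones (0.24, percentile 99.8, 5 genes), the G2 and M phases (0.06, percentile 99.6), heat shock proteins (0.07, percentile 99.4) and cholesterol synthesis (0.07, percentile 99.3). After removal of the GC and length trends cholesterol synthesis lay at percentile 93.4 and the G2 and M phases at 97.3, both inside, whereas the S phase (0.42) and TGF-beta and SMAD targets (0.17) lay outside. HSPA5 was at 177 RPKM with ATF3 against 183 in A2058, HSP90B1 at 338 against 328 and MANF at 88.9 against 88.0.

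**Figure D3:**
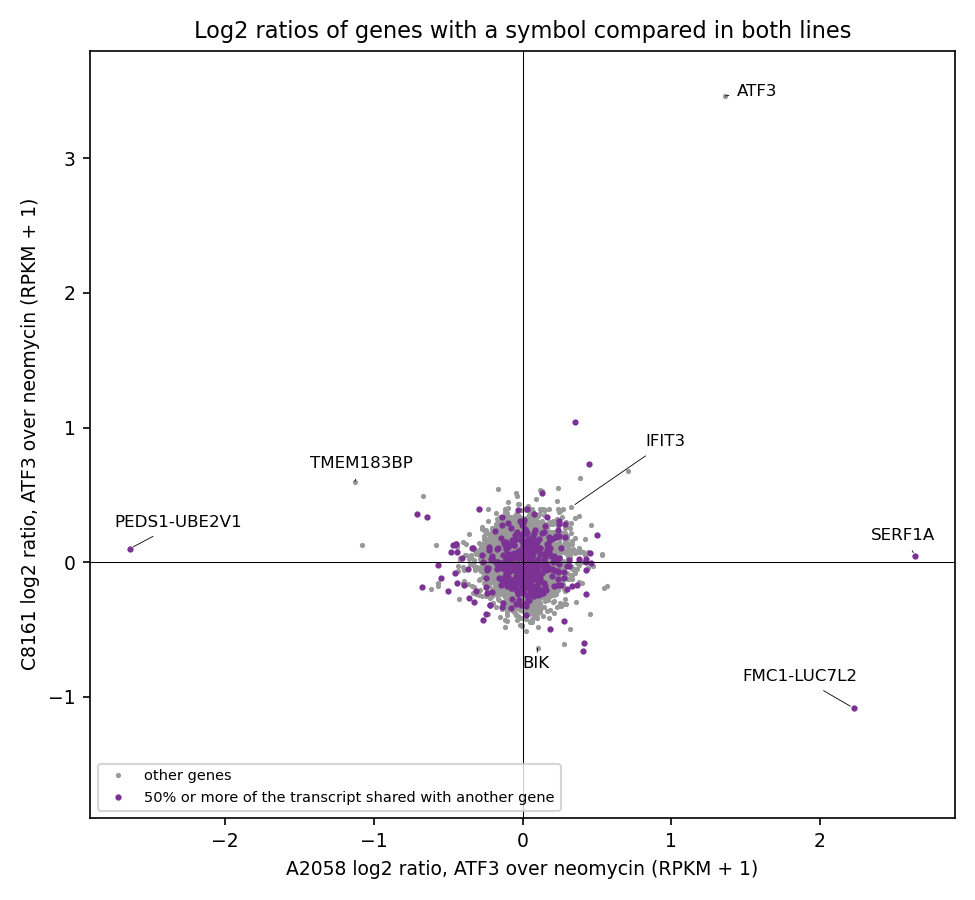
Log2 ratio of ATF3 over neomycin in A2058 (x axis) and in C8161 (y axis) for each gene with a symbol compared in both lines, on the log2(RPKM + 1) scale; purple points have 50% or more of their transcript sequence in another gene. ATF3 lies at 1.36 and 3.46, apart from the cloud of other genes around 0, and the points far to the left and right are mostly purple.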

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

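The tests of shared sequence in this part were chosen after the ratios were seen. In 8 named genes the log2 ratio lay above the level band in one line and below it in the other. Such calls were no more frequent over all genes than calls in the same direction. Of 259 genes above the C8161 band, 11 lay below the A2058 band and 19 above it. Of 268 below the C8161 band, 11 lay above the A2058 band and 11 below it. None of these differences between the lines was tested, since each rests on 1 value per arm. The log2 ratio in A2058 minus that in C8161 was 3.31 for FMC1-LUC7L2, −1.73 for TMEM183BP, 1.07 for LOC102724594, −1.06 for FAM72D, 0.89 for NBL1, 0.68 for EIF3CL, 0.54 for GDF15 and −0.33 for HSPA1A. GDF15, a stress-induced cytokine, was at 202 RPKM with ATF3 against 178 in A2058 and at 4.45 against 5.99 in C8161, where its log2 ratio was −0.36, and −0.21 after removal of the trends with GC content and length. The latter lies inside its band, which was taken from the uncorrected ratios. By that band, GDF15 lay below it in C8161 only without that removal. NBL1 was at 24.97 against 20.39 RPKM in A2058 and at 10.7 against 16.7 in C8161. HSPA1A, a heat shock protein with a near-identical neighbouring copy, was at 358 against 378 RPKM in A2058 and at 175 against 147 in C8161. It passed its bands narrowly, at −0.076 against an edge of −0.069 in A2058 and 0.252 against 0.243 in C8161.

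Large ratios gathered in genes that share their sequence with another gene. In A2058, 100% of the 8 genes past a log2 ratio of 1 that have a reference transcript were shared, but 13 genes other than ATF3 passed and only 61.5% of them have a transcript, so this test is void; in C8161, 66.7% of 3 such genes were shared, which is too few to decide. At a log2 ratio of 0.5 or more, 49.0% of 51 genes were shared in A2058 and 34.6% of 26 in C8161, against 4.65% and 4.07% of all genes and at most 15.7% and 15.4% in the central 95% of random sets matched on level. Reads assigned differently to near-identical genes may therefore lie behind part of the large ratios, and an effect of ATF3 on these genes cannot be told apart from it. CDH5, MSMP, STC1, IL24, BIK and TGFBI share 0% of their sequence, and for them this explanation has no basis.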

How the results depend on the processing

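No paired analysis was possible because the table gives 1 combined value per C8161 arm, and the A2058 arms have 1 library each. For the same reason the replicate block, leaving out each library, limma with and without its trend or robust option, the fits of all 8 libraries, the interaction, camera with either correlation and fry were not run. No named gene outside its level band and no list median outside the central 95% changed sign under any alternative run. Values inside these ranges did in places, as for TPGS1 in C8161 (−0.25 to 0.02 after the GC and length correction) and for the medians there of hypoxia and glycolysis (−0.02 to 0.03 after quantile normalization) and antigen presentation (−0.05 to 0.01 after the GC and length correction). Of the ratios of single named genes other than ATF3, 1740 values moved by less than 1 SD of the genes nearest in level and 42 by more; of list medians, 345 moved by less than 1 SD of random lists and 41 by more. The median ratio of all genes stayed within 0.01 of 0 under every scaling. With a pseudocount of 0.1 the ratio of ATF3 was 1.87 in A2058 and 3.69 in C8161, and 11 genes were higher and 25 lower by a log2 ratio of 1 in A2058, and 6 and 3 in C8161; with 0.5 the A2058 ratio of ATF3 was 1.60. This follows from the smaller constant, which shrinks low genes less. With a minimum of 5 RPKM, which leaves fewer genes, 1 gene was higher and 2 lower in A2058, 1 and 0 in C8161, and Pearson's r between the lines was −0.021. After the GC and length correction, which leaves out genes without a transcript, 4 genes were lower in A2058, and r was 0.0012. At a size of 0.5 the counts were 25 and 39 in A2058 and 20 and 10 in C8161; at a size of 1, without genes that have shared sequence or no transcript, they were 1 and 0 in A2058, and 0 lower in C8161. Of the 13 A2058 genes of that size so left out, 5 had no transcript, so that loss is not due to shared sequence alone. The last 3 settings were chosen after the data were seen. Of the 8 C8161 lists outside the central 95%, the same 8 stayed outside with both pseudocounts, with median-ratio scaling and without a minimum level, and 7 under each of quantile normalization, the 5 RPKM minimum and the GC and length correction. Of the 6 in A2058, 5 stayed outside under quantile normalization and under the GC and length correction, 4 without a minimum level and 3 with the minimum of 5 RPKM; these 3 were hypoxia and glycolysis, interferon and extracellular matrix. The cause of these losses was not tested. The ratios were spread most widely in A2058 at low levels, and counting error was not separated from other spread: the SD of the log2 ratio was 0.19 at 1 to 5 RPKM and 0.071 at 20 RPKM or more, against 0.13 and 0.14 in C8161, whose depth is unknown.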

Other observations

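Genes named in the first paragraphs of this part were chosen after their values were seen, as was the test of the ribosomal list by quantile normalization. The control cells of the lines differed far more from each other than either did from its ATF3 arm. Of 12372 genes with at least 1 RPKM in a control, 1158 were higher in C8161 and 2555 higher in A2058 by a log2 ratio of 1 or more, with 1 column per line and no test. Pearson's r of the log2 levels across these genes was 0.779 between the controls, and 0.998 between the ATF3 and control columns within each line. In A2058, 22 of 25 melanocyte lineage genes were higher. Among them were the pigment cell regulators SOX10 (254 RPKM against 0.06 in C8161) and MITF (54.0 against 0.95), the enzyme DCT (308 against 0.03), and PMEL (806 against 0.18). In C8161, 16 of 23 genes of the dedifferentiated state were higher, including the receptor kinases AXL (280 against 11.4 RPKM in A2058) and EGFR (46.2 against 0.07).

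C8161 controls also had more of 15 of 27 NF-kB and inflammatory cytokine genes, such as IL1B (46.4 against 0.85 RPKM) and CXCL8 (48.5 against 2.73), and of 3 of 5 endothelial markers, with TIE1 at 67.2 against 1.45 RPKM and ROBO4 at 20.5 against 0.03. The other 2 were higher in A2058, EGFL7 at 54.4 against 9.75 RPKM and ESAM at 1.70 against 0.28. Only these 5 endothelial markers reached 1 RPKM in a control. The rest of that list did not in either line, among them PECAM1 (0.11 RPKM in C8161 and 0.15 in A2058), VWF (0.02 and 0.12) and KDR (0.25 and 0.34). A2058 controls were higher in 12 of 29 hypoxia and glycolysis genes and 8 of 9 replication-dependent histone genes, with none of either list higher in C8161 by that size. The AP-1 partner FOSL1 was at 489 RPKM in C8161 and 45.4 in A2058, but of 23 genes of the AP-1 and ATF family 3 were higher in C8161 and 7 in A2058. ATF3 was thus introduced into cells with different levels of lineage regulators, and reached different levels in them.

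The differences of 5 lists in C8161, and of the interferon list in A2058, might follow from the GC content and length trend of the ratios. If so, their percentiles would have fallen between 10 and 90 after the trend was removed. They were 100 for interferon, 100 for the unfolded protein response, 99.57 for cholesterol synthesis, 99.86 for the integrated stress response and 0.11 for ribosomal proteins, and 99.2 for interferon in A2058, which argues against the trend as the whole cause, although the ribosomal median was −0.15 before and −0.06 after the removal. The heat shock list of C8161 lay at 98.4 before and at 96.0 after the removal. Its median stayed at 0.06, while the upper edge of the central 95% of random lists went from 0.0597 to 0.0657, so the call was lost by a small margin. The edge rose although the SD of the random lists fell, so the matched random lists themselves lay higher after the removal. The heat shock list thus stood less far above them. The trend may account for part of its difference, and is neither shown nor excluded as the cause. A scale that differs at the highest levels stays open for the ribosomal list, which lay at 3.55 after quantile normalization. An effect of ATF3, which acts in stress responses, is a hypothesis for the interferon and chaperone lists; differences between cultures or library preparations remain open too, since each arm has 1 value.

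The lack of a correlation between the lines could come from counting noise in low genes or from the opposite GC content and length trends. Across 3100 genes at 20 RPKM or more in both lines, Pearson's r was −0.050. After removal of both trends in both lines it was 0.0012, and with both steps together, across 3097 genes, −0.044. Either explanation had been predicted to give more than 0.2, and none of these values did. The limit of 0.2 presumes a shared effect that is large against the other spread of the ratios. A weak shared effect masked by noise or by the trends is therefore not excluded. The 13.1-fold and 3.86-fold higher ATF3 levels, the different starting states of the lines, and unreplicated technical variation remain open and were not tested.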
